A study of Homo sapiens with 6 samples.

How the data were processed

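Total RNA from SH-SY5Y cells, a human neuroblastoma line with a catecholamine-neuron character, was measured on 6 one-colour microarrays. Per the labels, 3 samples came from cells exposed to 500 µM manganese chloride for 6 h and 3 from cells kept for the same time without it. RNA was labelled with the dye Cy3 by linear amplification, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. Background correction, probe filtering and the normalization between arrays are not given in the sources used here. The labels call the 3 samples of a group biological replicates. The series description speaks of independent experiments with different donors, while every sample is labelled as the same cell line, and the sources used here do not settle what separates the samples of a group. The p-values therefore measure the spread between these samples, which may in part be technical.

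The deposited table holds log2 intensities for 111087 rows and 6 arrays, with no missing value. That the authors' values are log2 was read from their range of 1.82 to 19.1, since any other usual base would exceed what a scanner records. The sorted columns of the deposited table differed by at most 0.00327, and every array had a median of 5.50 and a 75th percentile of 8.00. Values forced to a single distribution in this way are what quantile normalization leaves, and they hide any change in the total amount of RNA. The values were not centred per probe. Detection flags and scanner files were not analysed here, so no probe was marked as detected or saturated.

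Of the rows, 68 were control rows by name and stayed out of the tests. The other 111019 were tested. They fell by name into 32776 catalogue probes (names starting A_) and 78243 custom probes (names starting CUST_, in 9 custom design numbers). The table gives no genes for these probes, and the reference used here lists genes without probe names, so probes were not named or classed as mRNA or lncRNA. For this reason the gene-level fit, the counts for protein-coding genes and for long non-coding RNAs, the 31 gene lists and the comparison of lncRNAs with neighbouring genes, all fixed before the data were examined, were not run. Only the control rows named for GAPDH and PGK1 give a human gene in their name. Both genes belong to the fixed glycolysis list and to the housekeeping list, which had under the 5 measured members needed for a test.

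The test was limma's lmFit and eBayes with default settings (limma 3.58.1 in R 4.3.3) on the deposited log2 values, manganese minus control, 3 arrays against 3, two-sided, with Benjamini-Hochberg adjustment over all 111019 probes and a threshold of 0.05. A log2 change of at least 1 in size is called 2-fold. The 4 rows of human GAPDH and PGK1 were tested in the same fit with these rows added. The named probes are the 2 largest rises and the 2 largest falls among probes that passed the test, had no overlap between the groups and had a higher group mean above the 40th percentile of all probe means. The rule was written for genes before the data were examined, with more places, and was held to 4 probes because they carry no gene name. As a background level, the higher of the negative-control row and the dark-corner row was taken on each array, between 2.17 and 2.41 on the log2 scale. The precision of each value is limited by the number of arrays.

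The fit was tested on simulated arrays drawn from the means and spread of the 111019 real probes. With 200 probes changed, 0% of changes of 0.5, 22.1% of changes of 1 and 62% of changes of 2 on the log2 scale were recovered at adjusted p 0.05, and 4 of 63 calls were false. With 20% of the probes changed, 51.9%, 76.1% and 92.5% were recovered for the same sizes, and 4.72% of calls were false. With nothing changed, 0 probes were called. Each simulated value was drawn independently, without a deviation shared by the probes of an array, such as the real arrays show. These values therefore do not show what share of the calls on the real arrays is false.

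Alternatives were a further quantile normalization, subtraction of each array's median or 75th percentile, leaving out the dimmest 40% of probes, an intensity trend with a robust prior, the replicate number as a block, leaving out each array in turn, an unmoderated test, and a threshold of unadjusted p under 0.05 with a 2-fold change. Averaging over a gene's probes and the alternatives for gene lists and neighbouring genes were not run, for want of gene names. A term for the split of the arrays seen in the spike-in rows, and limma array weights, were chosen after seeing the data. Whether the replicate numbers pair the arrays was checked with the correlation of the arrays' deviations from their group means. Figures were drawn with matplotlib 3.10.9.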

Results

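Expression was measured in SH-SY5Y cells, a human neuroblastoma line used as a model of dopamine neurons, after 6 h with 500 µM manganese chloride (3 arrays) and after 6 h without manganese (3 arrays). Manganese is an essential metal that harms dopamine neurons in excess, and the study set out to profile the coding and long non-coding transcripts that respond to it. Each array gave a log2 intensity for 32776 catalogue probes and 78243 custom probes. Between 79.5% and 84.5% of the probes lay above the background level on an array. The arrays share a single distribution of values, so this range reflects only the background level, which was highest on manganese 3 (2.41). The catalogue probes were brighter, with 82.7% above background on all 6 arrays against 67.1% of the custom probes. Values of 2 arrays differed by a root mean square of 0.474 to 0.555 between controls, 0.495 to 0.509 between manganese arrays and 0.597 to 0.667 between the groups.

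The first comparison asked which transcripts changed after 6 h of manganese. Transcripts of 2 glycolytic enzymes, GAPDH and PGK1, rose with manganese in 1 of the 2 human control rows that carry the name of each. The row Human-GAPDH_3 (glyceraldehyde-3-phosphate dehydrogenase, which oxidises a triose phosphate in glycolysis) went from 14.72 ± 0.12 in controls to 15.23 ± 0.05 with manganese (SD, n = 3 each). This was a 1.43-fold rise, with a log2 change of 0.51 ± 0.08 (SE) and an adjusted p of 0.0198 in limma. The row Human-PGK1_5 (phosphoglycerate kinase, an ATP-forming step of glycolysis) went from 9.44 ± 0.10 to 10.07 ± 0.13, a 1.55-fold rise with a log2 change of 0.63 ± 0.10 and an adjusted p of 0.0173 in limma. The second row of each gene did not pass the test. Human-GAPDH_5 had a log2 change of 0.31 ± 0.15 (adjusted p = 0.266 in limma), and Human-PGK1_3 one of 0.30 ± 0.10 (adjusted p = 0.134 in limma). In all 4 rows every manganese array lay above every control array, a pattern that chance gives to 5% of rows in 1 direction and that 9 of the 56 control rows of no mammalian gene showed as well. Both genes are often used as expression controls and stood on the housekeeping list as well as on the glycolysis list. In a limma fit with a term for the split of the arrays seen in the spike-in rows, manganese is set against control 3 alone. The control arm is then 1 array, so only log2 changes are given. They were 0.65 for Human-GAPDH_3, 0.60 for Human-GAPDH_5, 0.50 for Human-PGK1_3 and 0.74 for Human-PGK1_5. In most spike-in rows the manganese mean also lay above control 3 (by 0.41 in DCP_20_7, against -0.21 in DCP_20_9, both dimmer than the human rows). In spike-in rows as bright as the human rows it lay above by 0.07 ((+)E1A_r60_1) to 0.19 ((+)E1A_r60_n9), less than in the human rows. Part of these changes may therefore be an offset of that array. Without control 3 both calls held, with an adjusted p of 0.0188 for Human-GAPDH_3 and 0.0286 for Human-PGK1_5 in limma. Without control 1, control 2 or any 1 manganese array, Human-GAPDH_3 had an adjusted p of 0.0554 to 0.0744 in limma and was not called. Human-PGK1_5 was also called without manganese 3 (adjusted p = 0.0436 in limma), and without any 1 of the other arrays its adjusted p was 0.0520 to 0.0615.

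Across the array, 13956 of the 111019 probes (12.6%) changed with manganese at an adjusted p below 0.05 in limma. Of these, 5256 probes were higher and 8700 were lower, so that 62.3% of the changed probes fell (95% exact binomial interval 61.5% to 63.1%, which treats probes as independent). Intervals of this kind do not cover the spread between arrays. With 1 array left out the share was 53.6% (without control 3) to 69.9% (without manganese 3). The typical change was under 2-fold, with a median size of 0.662 on the log2 scale. Among the 3270 probes that changed at least 2-fold the excess of falls was larger, with 791 rises against 2479 falls (75.8% lower, 95% exact interval 74.3% to 77.3%). The median log2 change over all probes was 0.02, and 99% of all probes lay below 1.17 while 1% lay below -1.52. All 13956 changed probes had no overlap between the groups. In all, 36863 probes (33.2%) had no overlap, where chance gives 10%. The count depended on the arrays used. Without any 1 of the arrays other than control 3 it was 6087 to 7445, and without control 3 it was 21816, of which 53.6% fell. At 2-fold or more, the fit without control 3 called 1668 rises and 2866 falls (63.2% lower). With the split of the arrays seen in the spike-in rows as a term, control 3 is the only control set against manganese. Calls of that fit are therefore not counted here. Of the 13956 changed probes, 852 were at least 2-fold higher and 2180 at least 2-fold lower in it.

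**Figure D1:**
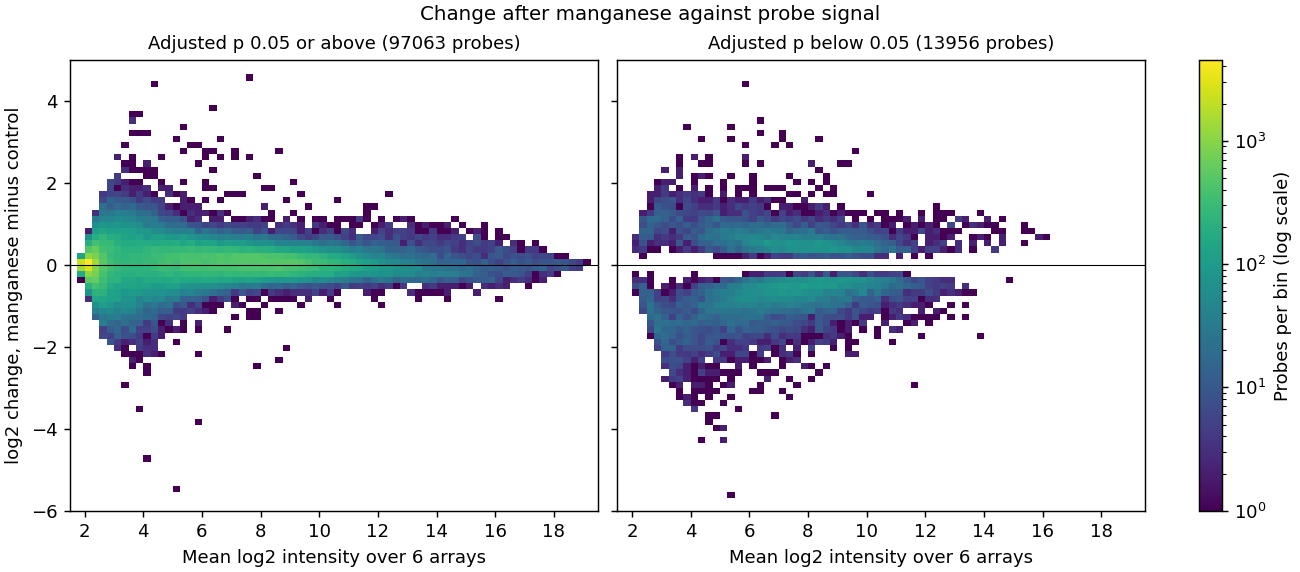
Each panel shows the log2 change of the tested probes (manganese minus control, 3 arrays each) against their mean log2 intensity over the 6 arrays, binned, with colour for the number of probes per bin on a log scale. Among the 13956 probes with an adjusted p below 0.05 (right), falls outnumber rises by 8700 to 5256 and reach larger sizes.

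The largest rise that met the rule was that of the custom probe CUST_79303_PI429545395, from 3.64 ± 0.69 in controls to 8.02 ± 0.10 with manganese (SD, n = 3 each). Its log2 change was 4.38 ± 0.35 (SE), 20.9-fold, with an adjusted p of 0.00349 in limma. The custom probe CUST_86146_PI429545395 rose 11.1-fold, from 4.75 ± 0.36 to 8.22 ± 0.08 (adjusted p = 0.00207 in limma). The largest fall was that of the catalogue probe A_23_P161218, from 8.07 ± 0.37 to 2.50 ± 0.20, with an adjusted p of 0.00161 in limma. Its manganese values of 2.36, 2.72 and 2.41 lay close to the background level of 2.22, 2.21 and 2.41 on the same arrays, so its 47.6-fold fall may be a lower bound. The custom probe CUST_59810_PI429545384 fell 20.3-fold, from 7.23 ± 0.26 to 2.89 ± 0.54 (adjusted p = 0.00269 in limma). Its values of 2.59 and 2.57 on manganese 1 and 3 also lay near background, unlike the 3.51 on manganese 2. This fold may therefore be a lower bound too. These 4 probes passed the test with every single array left out. The table does not name the genes behind them. Of the probes that fell, 225 were at or below background on all 3 manganese arrays, and of those that rose, 81 were at or below background on all 3 control arrays.

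The second comparison set the catalogue probes beside the custom probes, since the study measured known transcripts and long non-coding RNAs on one array. Which probes target long non-coding RNAs is not stated in the sources used here. Of the catalogue probes 5768 (17.6%) changed, 1939 higher and 3829 lower. Of the custom probes 8188 (10.5%) changed, 3317 higher and 4871 lower. With 1 array left out these counts lay between 2563 (without control 1) and 8401 (without control 3) for catalogue probes and between 3524 and 13415 for custom probes, again without control 1 and control 3. Custom probes were called less often, with an odds ratio of 0.547 (95% interval 0.528 to 0.568, Fisher's exact test, two-sided, p = 1.7e-222, adjusted over 2 tests 3.4e-222). The size of this difference depended on the threshold. At an adjusted p below 0.05 with a 2-fold change, 3.58% of the catalogue probes and 2.68% of the custom probes were called, and at an unadjusted p below 0.05 with a 2-fold change 4.10% (1343) and 3.90% (3055), where little of it was left. Falls made up 66.4% of the changed catalogue probes and 59.5% of the changed custom probes (odds ratio 0.744, 95% interval 0.693 to 0.798, Fisher's exact test, two-sided, p = 1.15e-16, also after adjustment). Several probes can measure one transcript, so these p-values are too small. Of the catalogue series, A_24 and A_23 had the highest shares of changed probes, at 21.6% and 20.9%, and A_33 the lowest, at 13.7%. Of the custom designs, PI429545410 had the highest share at 13.6% and PI429545376 the lowest at 6.28%. Falls outnumbered rises in all 6 catalogue series and all 9 custom designs. They made up 52.1% of the changed probes in PI429545402 and 77.1% in A_19.

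The share of probes called differed with their signal. In the dimmest decile of the probes, with means of 1.85 to 2.16, 4 probes (0.036%) changed, while in the decile with means of 6.49 to 7.48 it was 2512 (22.6%). The share was 22.5% and 20.3% in the next 2 deciles and 12.7% in the brightest, close to the 13.2% of the decile with means of 4.42 to 5.48. The spread between replicates was largest just above background, with a median residual SD of 0.579 for means of 2.51 to 3.30, and fell to 0.0959 for means of 8.52 to 9.82. It was 0.107 in the brightest decile and smallest, at 0.0407, in the dimmest. Falls made up over 60% of the changed probes in each decile of the signal except the lowest 2, where they were 25% of 4 and 51.4% of 138.

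Control 3 differed from the other controls in rows that hold no gene of the cells, of which 3 are named here, chosen after their values were seen. Rows named E1A detect RNA added during labelling on arrays of this maker, and rows named DCP were counted with them as spike-in rows from their names and levels. The row (+)E1A_r60_1 read 13.64 and 13.76 on controls 1 and 2, 13.21 on control 3 and 13.26, 13.21 and 13.36 on the manganese arrays. The row DCP_1_4 read 11.41 and 11.60 on controls 1 and 2, 10.66 on control 3 and 10.73, 10.77 and 10.87 on the manganese arrays. A probe for a synthetic standard, ERCC-00062_278, read 7.36 and 7.39 on controls 1 and 2, 7.99 on control 3 and 8.05, 7.92 and 7.88 on the manganese arrays. Over the 28 spike-in rows, controls 1 and 2 against the other 4 arrays explained 57.3% of the sum of squares, the largest share of all 31 ways to part the 6 arrays in 2, and the study's own groups explained 31%. Both splits set controls 1 and 2 against the manganese arrays, so their shares overlap and are not separate parts. The rows are not independent, and the split was uneven over them. The manganese mean minus that of controls 1 and 2 was -0.71 in DCP_1_4, but 0.01 in DCP_20_0 and 0.09 in (+)E1A_r60_n9. Over the tested probes the study's groups came first with 40%, followed by controls 1 and 2 against the rest with 34.4%, shares that overlap in the same way. On the first principal component (41.2% of the variance), controls 1 and 2 lay at -98.2 and -98.0, control 3 at -43.5 and the manganese arrays between 74.2 and 83.5.

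**Figure D2:**
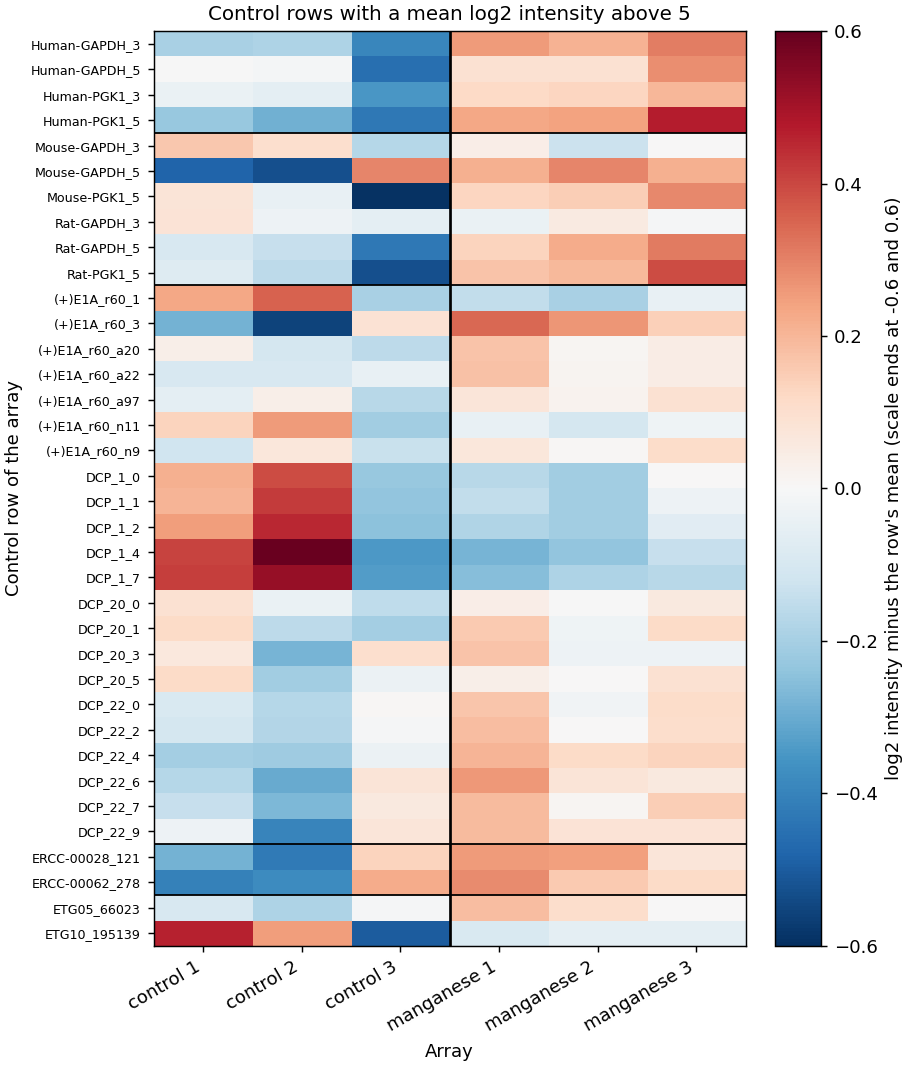
Colours give the log2 intensity minus the row's mean over the 6 arrays (columns) for the 36 control rows with a mean above 5 other than the bright-corner row, with lines between human gene rows, mouse or rat gene rows, spike-in rows (E1A and DCP), ERCC rows and ETG rows. The human GAPDH and PGK1 rows are higher on all 3 manganese arrays than on any control, while many spike-in rows part controls 1 and 2 from control 3 and the manganese arrays.

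Within the 4 arrays on the same side of the split in the spike-in rows only control 3 represents the unexposed cells. These 4 arrays were not alike in all spike-in rows. The manganese mean lay above control 3 in most of them, by 0.41 in DCP_20_7 and 0.29 in (+)E1A_r60_a135, both dim rows. In the brightest spike-in rows the difference was smaller, at 0.07 in (+)E1A_r60_1 and 0.10 in DCP_1_0. The manganese mean lay below control 3 only in DCP_20_3 (-0.07) and DCP_20_9 (-0.21). A comparison with control 3 alone carries this offset. In a fit with that split as a term, chosen after seeing the data, the manganese arrays are set against control 3 alone, and the spread is taken from controls 1 and 2 and from the manganese arrays, so that control 3 is assumed to vary like these. Calls of this fit would rest on 1 control array, to which the array weights gave the lowest weight (0.356), so only sizes are given. Of the 3270 probes changed at least 2-fold in the comparison of all arrays, 2676 (81.8%) differed at least 2-fold in the same direction from control 3 alone. Control 3 was part of the comparison that chose the 3270 probes, so much of this agreement in size follows from the choice. All 13956 changed probes kept their direction against control 3, which follows from their lack of overlap.

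**Figure D3:**
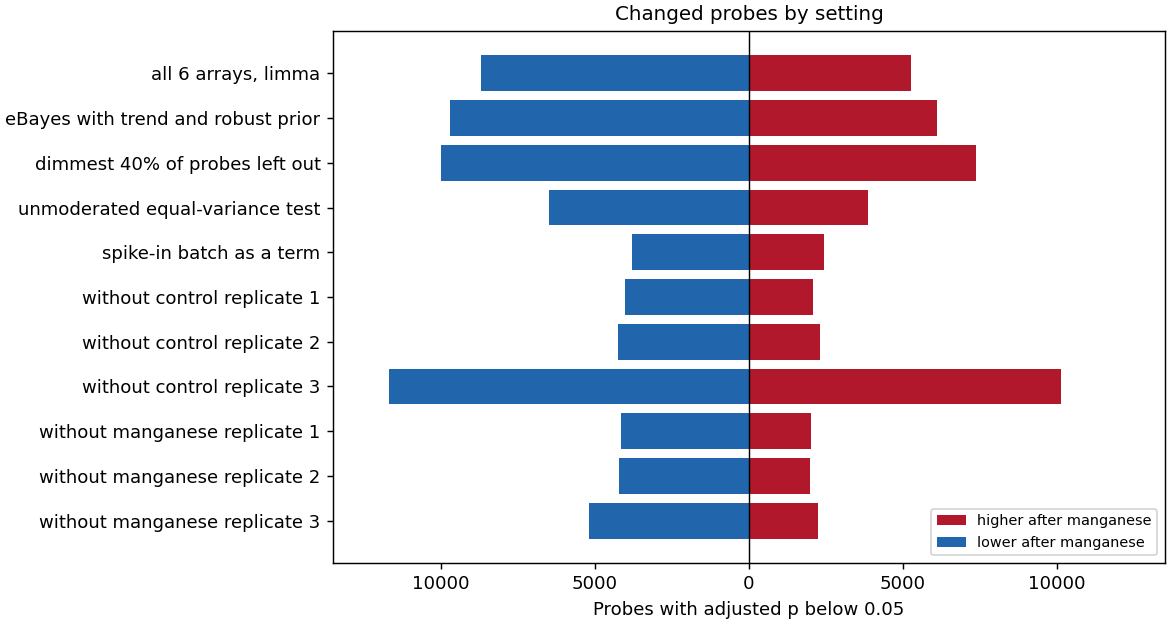
Bars show the number of probes with an adjusted p below 0.05 that were higher (right) or lower (left) after manganese, for all 6 arrays and for each alternative named on the left. Without control replicate 3 the counts rise to 10132 higher and 11684 lower, and without any other array they fall. The bars for the spike-in batch as a term rest on control 3 as the only control.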

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

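Of the tests in this part, those on the spike-in rows, on the normalization, on other splits of the arrays, on the shares by direction and on the ratios at other thresholds were chosen after the result was seen; the tests of a wrong label, of mixed RNA, of the split as the source of the falls and of probe signal were written down before theirs were seen. Among the 56 control rows of no mammalian gene, which lie outside the comparison, 9 had all 3 manganese arrays above all 3 controls, against 5% by chance, and 0 had them all below. Several of these rows detect the same added RNA, so they are not independent.

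Control 3 stood apart from controls 1 and 2, and without it the number of changed probes went from 13956 to 21816. A wrongly labelled manganese sample is argued against: of the 4534 probes changed at least 2-fold without control 3, only 30.5% (95% exact interval 29.2% to 31.9%) had control 3 nearer to the manganese mean. The share was 59.5% (57.1% to 61.8%) among the 1668 rises and 13.7% (12.5% to 15.0%) among the 2866 falls, so that the rises alone would not argue against a wrong label, while the falls do. RNA of exposed cells mixed into control 3 is argued against as the whole cause by the share of such RNA needed, computed per probe on the linear scale. The median share was 58.6% over probes that rose and 22.8% over probes that fell, a difference of 35.8 percentage points (bootstrap SE over probes 2.65). The shares varied between probes. In 303 (18.2%) of the rises control 3 lay below the mean of controls 1 and 2, which no share above 0 gives. A labelling or hybridization batch that control 3 shared with the manganese arrays remains open and may explain the split, with 57.3% of the spike-in rows' sum of squares lying between controls 1 and 2 and the rest. Over probes above the 40th percentile, the shifts of control 3 and of the manganese arrays, each taken against a different one of controls 1 and 2, had a covariance of 0.0791, which is 35.3% of the covariance between manganese arrays (0.224); the design gives no biological factor for control 3, so none was tested.

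More probes fell than rose. The split of the arrays stays open as a source of this. In the fit that has it as a term 61% of the called probes were lower (95% exact interval 59.7% to 62.2%), above the 50% set beforehand as the bound, but that bound was wrong for this design: the fit has control 3 as its only control, and an interval over probes does not cover the deviation of that array. Without control 3 the share was 53.6%. The normalization between arrays stays open too: it holds the median change near 0 (0.022) whatever happened to total RNA, so its part in the excess of falls cannot be told apart from an effect of manganese. The effect of manganese itself is the biological explanation the design gives, and it was not tested apart from these.

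Custom probes were called less often than catalogue probes, at a ratio of called shares of 0.595, at an adjusted p below 0.05. The pattern depended on the threshold: the ratio was 0.748 among calls that also changed 2-fold and 0.953 at an unadjusted p below 0.05 with a 2-fold change. For the calls by adjusted p alone, lower signal of the custom probes is argued against as the whole cause, since at matched deciles of mean signal the ratio was still 0.723 (95% bootstrap interval 0.702 to 0.745, over probes taken as independent). At the other thresholds the matched ratios were 0.733 and 0.883, without an interval. The kinds of transcripts behind the custom probes are the biological difference and remain open as untested.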

How the results depend on the processing

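The number of changed probes (13956) stayed within 1.5 times under the other scalings, the trend with robust prior (15807), the filter on dim probes (17363) and the unmoderated test (10384). The further quantile normalization and both subtractions moved no log2 change by more than 0.0206, since the table already had 1 distribution, and test nothing. Leaving out 1 array gave 6087 (without control 1) to 21816 (without control 3) changed probes, 2563 to 8401 catalogue and 3524 to 13415 custom probes; without control 2 it was 6568, and without manganese 1, 2 and 3 it was 6174, 6220 and 7445. The low counts come with fewer arrays, but so does the count of 21816. Leaving out control 1 or control 2 also gives control 3 more weight, and these causes were not told apart. Of the 21816, 12414 were among the 13956. With the spike-in split as a term there were 6227 changed probes, 2468 catalogue and 3759 custom; with array weights, which gave control 3 the lowest weight (0.356), there were 23074, 8971 and 14103; both were chosen after seeing the data. Among probes changed at least 2-fold, rises went from 791 to 1668 without control 3 (63.2% lower) and to 1333 with array weights (69.6% lower), against 75.8% lower with all arrays. A threshold of unadjusted p under 0.05 with a 2-fold change gave 4398 probes, 1343 catalogue and 3055 custom. With the replicate number as a block, limma called 0 probes, 0 at 2-fold and 0 of either class (lowest adjusted p 0.0623; 24682 probes at an unadjusted p under 0.05), with 2 fewer residual degrees of freedom. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.016, -0.012 and -0.087, and no control correlated best with its own number. The share of falls among changed probes lay between 53.6% (without control 3) and 70.6% (unadjusted p with a 2-fold change) in settings that called any. The ratio of the called shares, custom to catalogue, was 0.595 with all arrays. It was 0.953 under the unadjusted threshold with a 2-fold change and 0.513 to 0.813 in the others. At matched deciles of mean signal the ratio was 0.723 with all arrays and 0.883 under the unadjusted threshold. In the others the matched ratio was 0.662 (unmoderated test) to 0.834 (without control 3). Lower signal was the only cause tested. Named probes kept their direction in all settings, which follows from their lack of overlap between the groups. Spread just above background limits what can be called there.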

Other observations

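The test of neighbouring probe numbers was written down before its result was seen, after such numbers were noticed among the largest changes; the counts of splits and the values by gap were chosen after. Rows for mouse and rat genes gave signal on these human arrays, whose RNA came from human cells per the labels. Rat-GAPDH_5 had a mean of 11.57 on controls 1 and 2, a value of 11.26 on control 3 and a mean of 11.91 with manganese, and Rat-PGK1_5 went from 8.48, 8.40 and 8.03 to 8.73, 8.75 and 8.95, the same direction as the human rows. Mouse-GAPDH_5 instead read 9.52 and 9.47 on controls 1 and 2 and 10.29 on control 3, beside 10.21, 10.29 and 10.21 on the manganese arrays. Of these 8 rows, 5 had all manganese arrays above all controls.

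Custom probes with neighbouring numbers changed more alike than re-paired ones. Over 69247 consecutive pairs with numbers at most 10 apart in the same custom design, the log2 changes had a Spearman rho of 0.112, where the highest of 1000 re-pairings within the design was 0.014 (permutation p = 0.001, the smallest that 1000 re-pairings can give). The rho did not fall steadily with the gap between consecutive numbers: it was 0.164 for gaps of 1 to 5 (1428 pairs), 0.111 for 6 to 10 (67819 pairs), 0.135 for 11 to 20 (6910 pairs) and 0.073 for 21 to 50 (2032 pairs). For the 23733 pairs with both probes above the 40th percentile of signal, rho was 0.232. Of the 1572 pairs with both probes called, 1292 (82.2%) went in the same direction, where independent directions would give 51.7%. Probes with close numbers may measure the same or neighbouring transcripts. The deviations of replicates within a group had a mean rho of 0.021 over the same pairs. A mean of this kind cannot show an effect common to all arrays of a group, and it may dilute that of a single array. Neighbours also resembled each other in signal (Spearman rho 0.225), on which the re-pairings within the design were not matched. Probes are not independent, and counts of changed probes are not counts of changed transcripts.

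Of the 10 ways to part the 6 arrays into 3 and 3, the study's groups gave 13956 changed probes, and the highest of the others gave 0. This is 1 split of 10, and 10 splits are too few for a share under 0.05. Each of the other splits also mixes control and manganese arrays within a part. The difference between the study's groups then adds to the spread, so low counts there follow in part from the design.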
